A study of Homo sapiens with 12 samples.

How the data were processed

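Gene expression was measured by Illumina HT-12 v4 beadchips in 12 samples of human myeloma cells, each a single array: JJN-3 and a line labelled RPMI, treated with DMSO, GSK-J4, GSK-J5 or bortezomib for 6 h or 24 h. The labels do not say which RPMI line was used, and no replicate cultures or slide positions are given in the sources used here. Total RNA was isolated with Trizol, checked for quality and amplified with a TotalPrep kit, per the labels' protocols.

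The authors deposited probe intensities before normalization for every array, with a detection p-value beside each intensity, per the file headers. The intensities had not been background-subtracted, and the detection p-values compare each probe with the negative controls of its array. The authors also deposited a table of processed values on a log2 scale. In that table the 5 arrays of 24 h share a single distribution and the 7 arrays of 6 h another, with medians of 6.59 and 6.50, so the sets had been normalized separately. The software behind either table is not given in the sources used here.

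The rows of the deposited intensities had to be realigned before use. The 47224 probe identifiers are as many as the rows of the 24 h arrays, while the 7 arrays of 6 h hold 47231 values and are shifted by a growing number of rows. The shift was located by matching the 6 h signals to the 24 h signals, which gave 7 breaks, the first at row 10570, and 50 rows on each side of every break were left out (700 in all), leaving 46524 probes. The correlation of mean log2 signal between JJN-3 at 24 h and at 6 h rose from 0.397 as deposited to 0.980 after alignment. In a simulation of 21 breaks the largest error was 5 rows. As a check, the levels of probes of the same gene were correlated with the rows at the assigned place and at other shifts. Within a segment between breaks the assigned place gave the highest correlation in 7 of 8 segments at both times. In segment 3 it did not (221 pairs, r = 0.0017 against 0.183 elsewhere at 6 h, and −0.0066 against 0.207 at 24 h). Between a segment and the others the assigned place was also highest in 7 of 8, including segment 3 (408 pairs, 0.496 against 0.109 at 6 h, and 0.563 against 0.145 at 24 h), but not in segment 7 (43 pairs, 0.21 against 0.395, and 0.124 against 0.413), so each of these 2 segments rests on 1 of the 2 checks. The identifiers of the deposited log2 table fitted 1.25% of its rows for the 24 h arrays and 0% for the 6 h arrays, so its values were matched to probes through their ranks within each array. Of the probes, 30110 had a single gene symbol, 8 had several and 17106 were unnamed here. Gene identifiers of 30071 probes were found in the RefSeq table, and 0 symbols needed an update.

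Background correction, quantile normalization and log2 transformation were done together over the 12 arrays with limma's neqc (limma 3.58.1, R 4.3.3, offset 16), with the background estimated from the detection p-values. Probes with a detection p-value under 0.01 in at least 1 array were kept, 20320 in all, 15287 with a gene name and 5033 without. Each of 11459 genes was represented by its named probe with the highest mean. Array depth is given as the number of probes detected, between 13837 and 16581. The 95th percentile of raw intensity lay between 842 and 1166 in the 24 h arrays and between 1180 and 2032 in the 6 h arrays, so low signals at 24 h limit the precision of weakly expressed genes. Where a gene was detected on no array of the lower side, its fold was computed against the lowest detected level and is given as "at least" that fold. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

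Comparisons of GSK-J4, GSK-J5 and DMSO at 2000 nM used 9 arrays in a limma model with context (JJN-3 at 24 h, JJN-3 at 6 h, RPMI at 6 h) and treatment as terms, so that the 3 contexts act as replicates (4 residual degrees of freedom). The same model gave the differences between lines at 6 h and between times. Single treated arrays were tested in a second limma model over all 12 arrays, in which the DMSO and GSK-J5 arrays of a context share a control mean. There the lone treated arrays are assumed to vary like the controls, and any effect of GSK-J5 counts as noise. The times form separate sets of arrays in the deposited tables, so a difference between times is also one between sets, and whether the sets were run together is not given in the sources used here. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Counts of genes over 2-fold between a treated array and its DMSO array had no test.

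A set of 28 gene lists was fixed before the data were examined, as were the models, the filter and the rule for naming genes. The lists cover the integrated stress response, amino acid supply, tRNA charging, endoplasmic reticulum chaperones, heat shock, metal response, antioxidant response, proteasome, sterol synthesis, hypoxia and glycolysis, cell cycle, plasma cell and myeloma genes, ribosome biogenesis, p53 targets, BCL2 family, NF-kB targets, interferon response, H3K27 and Jumonji demethylases, HOX genes, immediate early genes, autophagy, respiratory chain, ribosomal proteins, reference genes and markers of T cells, monocytes, erythroid and fibroblast or epithelial cells. They were tested with camera at a correlation of 0.01 and at an estimated correlation, and with fry, which tests only whether the genes of a list move one way. For single pairs of arrays a list's median was ranked among 10000 random lists matched on mean expression. Genes of a real list can vary together, which random lists do not reproduce, so an extreme percentile alone does not show an effect of treatment. Pairs with GSK-J5 also reached percentile 0.2 (respiratory chain, 500 nM) and 99.96 (amino acid supply, 2000 nM in RPMI). The rule named the 10 highest and 10 lowest genes past the threshold with 1 sign in all contexts for GSK-J4 against DMSO, the 10 highest and 10 lowest over 2-fold for bortezomib, the 5 highest and 5 lowest elsewhere, 2 to 4 members of each list described, and always KDM6A, KDM6B, ATF4, DDIT3, MYC, IRF4 and MT2A. Unnamed, pseudogene and uncharacterized loci were passed over.

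The models were tested on simulated data with 200 of 11459 genes changed. The changed genes were drawn from those above the median level, with the same change in every context. Noise was independent between arrays, with gene variances drawn around an SD of 0.133 from the pooled-control model, against 0.147 in the context model. The shares recovered therefore do not extend to dim genes or to changes that differ between contexts. For GSK-J4 against DMSO 95% of 2-fold and 100% of 4-fold changes were recovered with 11 false calls, for GSK-J4 in JJN-3 at 6 h 67% and 98% with 6, and for bortezomib 69% and 98% with 6. With nothing changed there were 0 calls for GSK-J5.

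Alternatives tried were quantile normalization with no background correction, the authors' processed values, no filter on dim probes, detection in at least 3 arrays, an intensity trend in limma, all named probes, no context term, leaving out a context or a control array, the GSK-J5 array as control, other fold limits and an estimated correlation. A pair of alternatives was chosen after seeing the data: normalizing the 24 h and 6 h arrays separately, and using only the rows before the first break, which needed no realignment.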

Results

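Gene expression was measured on Illumina HT-12 beadchips in JJN-3, a human plasma cell leukemia line used as a model of multiple myeloma, and in cells labelled RPMI, for which the labels give no further name. The compounds were GSK-J4, an ethyl ester prodrug of an inhibitor of the H3K27 demethylases KDM6A and KDM6B, GSK-J5, the ester of an inactive regioisomer of that inhibitor, and bortezomib, a proteasome inhibitor. Each of the 12 conditions had 1 array. JJN-3 cells were treated for 24 h with DMSO, GSK-J4 or GSK-J5 at 2000 nM, or GSK-J4 or GSK-J5 at 500 nM (5 arrays), and for 6 h with DMSO, GSK-J4 or GSK-J5 at 2000 nM, or bortezomib at 10 nM (4 arrays). RPMI cells were treated for 6 h with DMSO, GSK-J4 or GSK-J5 at 2000 nM (3 arrays). Between 13837 and 14378 probes were detected per array in the 24 h arrays and between 15601 and 16581 in the 6 h arrays. In all, 11459 named genes were detected in at least 1 array. Because no condition was replicated, the p-values measure only the spread between these arrays and contexts, and the small number of arrays limits the precision of every value.

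The comparison of GSK-J4 with DMSO asked which genes respond to the active prodrug in every setting, with the 3 contexts (JJN-3 at 24 h, JJN-3 at 6 h and RPMI at 6 h) as the replicates. The largest changes with GSK-J4 at 2000 nM were the rises of 5 metallothioneins, small cysteine-rich proteins that bind zinc and copper. MT1G was higher by 6.08 on the log2 scale (SE 0.745, n = 3 contexts, limma adjusted p = 0.00662), MT2A by 4.63 or 24.7-fold (SE 0.709, limma adjusted p = 0.0184), and MT1F by 3.79 or 13.9-fold (SE 0.349, limma adjusted p = 0.000867). MT1H was at least 37.0-fold higher (limma adjusted p = 0.0149), although its other detected probe was higher by only 1.20 on the log2 scale. MT1E rose by 4.74, and MT1X rose less (2.28). MT1F was detected on no control array at 24 h, so its mean change rests partly on a level not well above background. MT1G and MT1E were detected on only 1 of 3 control arrays at 24 h, so their mean changes are uncertain too. The members of this family are near-identical in sequence, so the share of each single gene is uncertain. Of 9 measured genes of the metal response list, 7 rose and 1 fell, and 8 and 1 passed when adjusted over the list alone. SLC30A1, the zinc exporter, was the other gene that rose (1.12), and SLC39A10, a zinc importer, fell by 0.79, which did not pass with the authors' processed values (−0.32, limma adjusted p = 0.0632). The list stood above the other genes by camera (adjusted p = 3.04e-10), with adjusted p = 0.138 with an estimated correlation. The sizes differed between contexts, with an SD over the 3 contexts of 2.30 for MT2A and 2.62 for MT1G, against 0.46 for DDIT3 and 0.33 for SESN2. DDIT3 was detected on no control array at 24 h, so its SD rests partly on a level not well above background.

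The integrated stress response, the translational stress program run by the transcription factor ATF4, rose with GSK-J4 in all 3 contexts. INHBE, an activin subunit gene induced by that program, was 10.9-fold higher (log2 change 3.44, SE 0.212, limma adjusted p = 0.000197). SESN2, a stress-induced inhibitor of mTORC1, was 6.54-fold higher (2.71, SE 0.184, limma adjusted p = 0.000197), and CHAC1, which degrades glutathione, was higher by 2.35 (SE 0.184, limma adjusted p = 0.000326). DDIT3, which encodes the transcription factor CHOP, was higher by 2.22 (SE 0.158, limma adjusted p = 0.000218), and ATF4 itself by 0.74 (SE 0.103, limma adjusted p = 0.0129). DDIT3 was detected on no control array at 24 h and CHAC1 on none in JJN-3 at 6 h. Their mean changes rest partly on levels not well above background. Of 14 measured regulators and targets of the program, 10 rose and none fell, among them DDIT4 (2.18), STC2 (1.52) and ATF3 (1.51). Adjusted over the list alone, 12 rose and 1 fell. The camera adjusted p was 1.4e-22, and the adjusted p = 0.12 with an estimated correlation.

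As lists, genes that supply amino acids and genes that charge tRNAs were also shifted upward, with median log2 changes of 0.754 and 0.289. Of the 18 tRNA genes 13 did not pass. Of 19 measured genes of amino acid synthesis and transport, 13 rose and none fell, and 18 rose when adjusted over the list alone. CTH, which makes cysteine, was higher by 2.02 (SE 0.139, limma adjusted p = 0.000197), the glycine transporter SLC6A9 by 1.80, PSAT1 of the serine pathway by 1.62, and ASNS, which makes asparagine, by 1.28. The list's camera adjusted p was 1.02e-28, with adjusted p = 0.12 with an estimated correlation. Of 18 measured genes for tRNA charging and export, 5 rose (SARS1 by 0.84, WARS1 by 0.79, MARS1 by 0.74 and AARS1 by 0.63 among them), and 8 rose when adjusted over the list alone. The camera adjusted p was 2.94e-08, with adjusted p = 0.12 with an estimated correlation.

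By fry, which tests whether a list's genes move one way without comparing them with other genes, these 4 lists had adjusted p = 0.0045, 0.0045, 0.00465 and 0.0331 for integrated stress response, amino acid supply, tRNA charging and metal response. Smaller shifts were seen in 6 further lists, of which heat shock (0.127) and sterol synthesis (0.161) did not pass fry. Autophagy and lysosome genes were shifted upward as a list (camera adjusted p = 0.00125, adjusted p = 0.125 with an estimated correlation), with 1 of 16 measured genes past the test, ULK1, the kinase that starts autophagy (0.90, limma adjusted p = 0.006), and 3 when adjusted over the list alone. The p53 targets were also shifted upward (camera adjusted p = 0.00907, adjusted p = 0.138 with an estimated correlation). Of their 10 measured genes, 1 rose, the death receptor gene TNFRSF10B (0.76), and 2 rose when adjusted over the list alone, while CDKN1A was at 0.77 with limma adjusted p = 0.0509. Heat shock genes were shifted downward (camera adjusted p = 0.000703, adjusted p = 0.359 with an estimated correlation), with 1 of 16 measured genes past the test, HSPA1B (−0.83, SE 0.114, limma adjusted p = 0.0124), which is near-identical to HSPA1A. Adjusted over the list alone, 1 heat shock gene rose and 5 fell. The heat shock median against the DMSO array was −0.37 in JJN-3 at 24 h and −0.24 at 6 h (both at percentile 0 of random lists), and −0.02 in RPMI (percentile 45.8). Sterol synthesis genes were shifted downward (camera adjusted p = 0.00153, adjusted p = 0.353 with an estimated correlation), with 1 of 11 measured genes past the test, MSMO1 (−0.55), and 3 lower when adjusted over the list alone. Their medians were −0.50, −0.21 and 0.02 in the same order (percentiles 0, 0.42 and 53.6). A percentile as low as 0.2 was also reached with GSK-J5 at 500 nM, by the respiratory chain list. Nucleolar ribosome biogenesis genes were shifted downward with 0 of 16 measured genes past the test and 2 lower when adjusted over the list alone (camera adjusted p = 0.00125, adjusted p = 0.138 with an estimated correlation). Proteasome subunits had a mean log2 change of −0.10 with 0 of 27 past the test either way (camera adjusted p = 0.00939, adjusted p = 0.138 with an estimated correlation). Without the RPMI arrays the proteasome list no longer passed (0.109), without the JJN-3 6 h arrays neither ribosome biogenesis (0.058) nor p53 targets (0.0518) passed, and without the JJN-3 24 h arrays sterol synthesis did not pass (0.181).

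The other 18 lists did not pass camera for GSK-J4 against DMSO. Their single genes past the test were HSPA5, the main chaperone of the endoplasmic reticulum, which fell by 0.57 (list adjusted p = 0.573), VEGFA of the hypoxia and glycolysis list, which rose by 0.76 (0.394), the BCL2 family genes HRK and PMAIP1, both promoters of apoptosis, which rose by 0.96 and 0.94 (0.163), and KDM4A of the H3K27 and Jumonji demethylase list, at least 1.42-fold higher (0.163). Adjusted over each list alone, these lists had 3 higher and 3 lower of 19 (endoplasmic reticulum chaperones), 1 and 1 of 17 (hypoxia), 3 higher of 13 (BCL2 family) and 2 higher of 15 (demethylases). Plasma cell and myeloma genes (0.376) and the antioxidant response (0.889) had 0 members past the test and 1 higher each when adjusted over the list alone. No member passed either way for cell cycle (0.163), NF-kB targets (0.83), interferon response (0.712), HOX genes (0.945), immediate early genes (0.773), respiratory chain (0.105), ribosomal proteins (0.485) or reference genes (0.489). Markers of other cell types did not pass either, with 0.959 for T cells and for monocytes, 0.977 for erythroid cells and 0.889 for fibroblast and epithelial cells. With the authors' processed values the respiratory chain list passed (0.0348, mean −0.08), and without the JJN-3 6 h arrays the hypoxia and glycolysis list passed (0.026). The drug target KDM6A was at 0.30 (95% confidence interval 0.035 to 0.563, limma adjusted p = 0.301), and KDM6B had no probe detected on any array. KDM6A was detected on no RPMI array in this model, so its mean changes with either compound include a context not well above background. MYC was at −0.06 (limma adjusted p = 0.841) and IRF4, a factor on which myeloma cells depend, at 0.28 (limma adjusted p = 0.339).

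Fewer genes fell with GSK-J4. Beside HSPA1B and SLC39A10, the lowered genes with the largest changes were CSTF1 of the mRNA cleavage machinery (−0.86, SE 0.150), the circadian repressor BHLHE41, the tubulin gene TUBB4B (−0.72), the stress granule gene G3BP1 (−0.71), TMEM158 (not past the test with the authors' processed values, −0.24, limma adjusted p = 0.0967), the antiviral gene ZC3HAV1 (−0.60) and the noncoding RNA genes SNORA16A (−0.66) and SNHG12 (−0.59). Other detected probes gave −0.31 and −0.20 for CSTF1, and 0.14 and −0.35 for ZC3HAV1, so these values hold for the probes used. In all, 76 genes rose and 14 fell, 31 of the 90 by more than 2-fold. At an unadjusted p under 0.05 by limma there were 1605 genes, against 573 by chance. All 90 had the same sign in all 3 contexts, which passing this test nearly requires. Among all genes 33.4% had 1 sign in all 3 contexts, against 25% by chance. Of the calls 84.4% were upward, against 70.5% of 315 with plain quantile normalization and 70.9% of 251 with the authors' processed values. Without 1 context the count was 12 (without RPMI), 19 (without JJN-3 at 6 h) or 40 (without JJN-3 at 24 h), and it was 51 with no filter on dim probes.

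GSK-J5 served as the control compound at the same dose and times. No gene passed for GSK-J5 against DMSO by limma, with 359 genes at an unadjusted p under 0.05 and 573 by chance. The residual of this model also holds the spread of the GSK-J4 changes between contexts. The test is therefore weak at genes where that spread was wide, such as MT2A, and these counts do not show that GSK-J5 was inactive. Of the 76 genes raised by GSK-J4, 63 were above 0 with GSK-J5 (median 0.116), and of the 14 lowered, 0 were (median −0.130). Both comparisons share the DMSO arrays, which pushes these values the same way, so a small effect of GSK-J5 is neither shown nor excluded. The differences for MT2A were 0.06 (95% confidence interval −1.53 to 1.64), for DDIT3 0.17 (−0.18 to 0.52), for ATF4 0.25 (0.021 to 0.482), for KDM6A 0.09 and for MYC −0.08. Among genes with the lowest p were OTUD6B-AS1 at 0.57 and SLC22A4, a carnitine-related transporter gene, at 0.46, both with limma adjusted p = 0.999. No list passed camera. The lowest was amino acid supply at adjusted p = 0.0996, which passed with plain quantile normalization (0.0314) and with the authors' processed values (0.0306).

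The direct test between the 2 isomeric esters at 2000 nM gave 45 genes higher and 1 lower with GSK-J4. MT1G was higher by 5.91 with GSK-J4 than with GSK-J5 (SE 0.745, limma adjusted p = 0.00893), MT2A by 4.57 (95% confidence interval 2.98 to 6.16, limma adjusted p = 0.0268), MT1F by 3.80 (limma adjusted p = 0.001), MT1E by 4.53, and MT1H was at least 37.4-fold higher. DDIT3 was higher by 2.05 (SE 0.158, 95% confidence interval 1.69 to 2.40, limma adjusted p = 0.000567). It was not detected with GSK-J5 at 24 h, so this size is uncertain. The lower gene was HSPA1B (−0.75, limma adjusted p = 0.0237). The difference between compounds did not pass the threshold at ATF4 (0.49, interval 0.256 to 0.716, limma adjusted p = 0.0999), which passed with plain quantile normalization (0.00643) and the authors' processed values (0.00657), at KDM6A (0.21, −0.051 to 0.477) or at MYC (0.02, −0.21 to 0.257).

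By list, integrated stress response genes (9 of 14 rose, and 13 rose and 1 fell adjusted over the list alone), amino acid supply (8 of 19, 18 alone) and tRNA charging (2 of 18, 7 alone) were higher with GSK-J4 than with GSK-J5, at camera adjusted p = 1.64e-25, 1.67e-30 and 1.22e-07, and at adjusted p = 0.101, 0.103 and 0.103 with an estimated correlation. The metal response list was higher with 6 of 9 genes past the test (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.59e-12, adjusted p = 0.117 with an estimated correlation). Autophagy genes had 1 of 16 past the test and 3 alone (0.00251, adjusted p = 0.114 with an estimated correlation), and p53 targets 0 and 2 alone (0.000136, adjusted p = 0.103 with an estimated correlation). Heat shock genes were lower (1 of 16 fell, and 1 rose and 4 fell adjusted over the list alone, 0.000136, adjusted p = 0.39 with an estimated correlation), as were ribosome biogenesis (0.000136, adjusted p = 0.114 with an estimated correlation) and sterol synthesis genes (0.0298, adjusted p = 0.619 with an estimated correlation), the last pair with 0 single genes past the test, and 0 and 2 lower adjusted over each list alone. Without the JJN-3 24 h arrays the sterol list did not pass against GSK-J5 (mean −0.05 against −0.15, adjusted p = 0.664) and the BCL2 family did (0.00426), as it did with plain quantile normalization (0.0364). The hypoxia list passed without the JJN-3 6 h arrays (0.00485) and the proteasome list with the authors' processed values (0.0397). Of the 76 genes raised against DMSO, 42 also passed against GSK-J5, and of the 14 lowered, 1. Of the 46 calls 97.8% were upward, against 80.8% of 156 with plain quantile normalization and 76.8% of 142 with the authors' processed values, and without 1 context the count was 5 (without RPMI), 16 (without JJN-3 at 6 h) or 30 (without JJN-3 at 24 h).

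**Figure D1:**
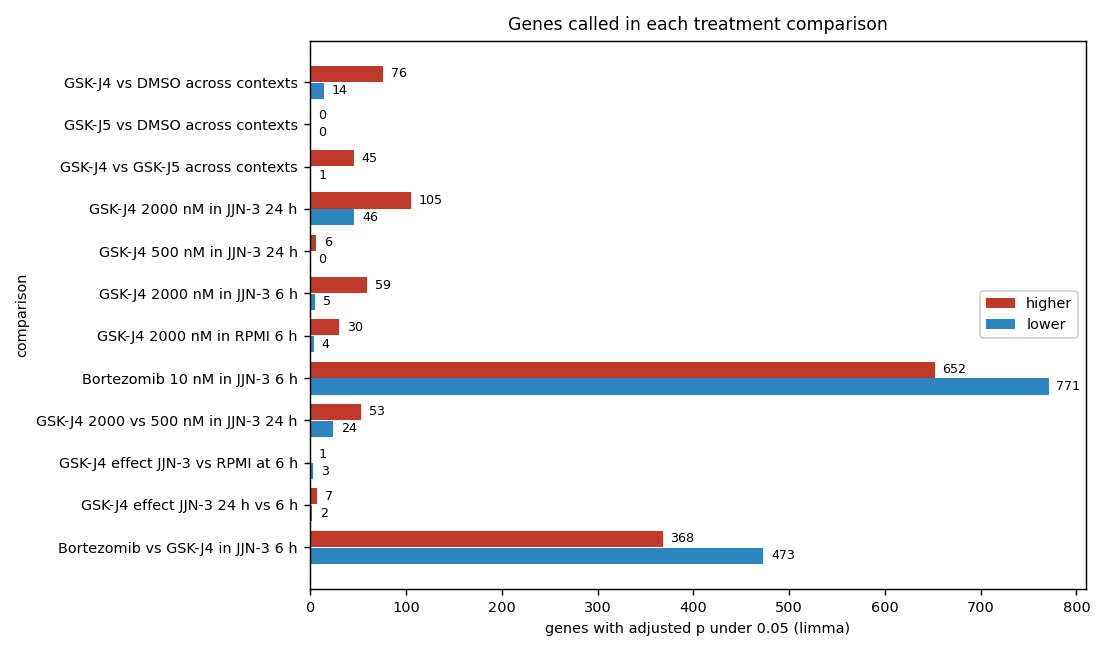
Bars give the number of genes higher and lower with limma adjusted p under 0.05 (horizontal axis, genes) for each of 12 treatment comparisons. GSK-J4 gave 76 genes higher and 14 lower across contexts, GSK-J5 gave 0, and bortezomib gave 652 higher and 771 lower.

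In JJN-3 at 24 h the dose of GSK-J4 could be compared. At 2000 nM MT1G was higher by 8.87 than in the pooled DMSO and GSK-J5 arrays (SE 0.286, limma adjusted p = 1.2e-06), MT2A by 6.29 (SE 0.117, limma adjusted p = 4.39e-08), and MT1H at least 144-fold. At 500 nM MT1G was higher by 7.37 (SE 0.286, limma adjusted p = 7.73e-06), MT2A by 4.52 (SE 0.117, limma adjusted p = 7.41e-07) and MT1X by 2.80, MT1H was at least 22.5-fold and MT1F at least 3.78-fold higher, and MT1E rose as well. These 6 metallothioneins were all the genes that passed at 500 nM. Of the integrated stress response (14) and amino acid supply (19) genes, 0 passed at 500 nM and 8 and 5 at 2000 nM (12 rose and 1 fell, and 16 rose, when adjusted over the list alone). DDIT3 was at least 4.40-fold higher at 2000 nM and did not pass at 500 nM (limma adjusted p = 0.528). Against the 24 h DMSO array alone, MT2A was at 4.52 with 500 nM GSK-J4 and at −0.01 with 500 nM GSK-J5. MT1G was detected on only 1 of 3 control arrays at 24 h, so its sizes at both doses are uncertain.

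In the single array with 2000 nM GSK-J4 at 24 h, hypoxia and glycolysis genes were also lower. PFKFB4, a hypoxia-inducible regulator of glycolysis, was at least 8.97-fold lower (limma adjusted p = 7.62e-06), and KDM3A (−0.95), NDRG1 (−0.84), PFKFB3 (−0.84) and HK2, the first enzyme of glycolysis (−0.71), fell with it. Of 17 measured genes of that list, 6 fell, and 12 fell and 1 rose adjusted over the list alone. The median of the list against the DMSO array, −0.54, lay at percentile 0 of 10000 random lists of like expression (random medians −0.147 to 0.105), as did those of sterol synthesis (−0.50), heat shock (−0.37) and cell cycle genes (−0.28). Among heat shock genes BAG3 (−1.17), HSPA1B (−0.86) and DNAJB1 (−0.80) fell and SERPINH1, the collagen chaperone, rose (0.75). AURKA, a mitotic kinase, fell (−1.04, limma adjusted p = 0.00498). CCL3, a chemokine, rose by 1.27.

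In all, 105 genes rose and 46 fell at 2000 nM and 6 rose and 0 fell at 500 nM (689 at an unadjusted p under 0.05). The count at 2000 nM depended on processing, with 172 and 95 with plain quantile normalization, 79 and 24 with the 24 h arrays normalized by themselves, and 117 and 40 with the authors' processed values, which shared 72 of the 151 calls. The 2 doses differed at 77 genes, 53 higher and 24 lower at 2000 nM, among them INHBE (3.49, limma adjusted p = 0.022), CHAC1 (2.39), MT2A (1.77, limma adjusted p = 0.00214), DDIT3 (limma adjusted p = 0.0144), the adhesion gene FERMT2 (2.12) and PFKFB4, at least 11.1-fold lower. By list, 7 of 14 integrated stress response, 5 of 19 amino acid supply and 5 of 9 metal response genes were higher at 2000 nM and 1 of 17 hypoxia genes was lower, with 12 higher and 1 lower, 16, 7 and 11 when adjusted over each list alone. Of these 77 calls 68.8% were upward, against 79.8% with the authors' processed values and 89.1% of 46 with the 24 h arrays normalized by themselves. Several of the lowered genes ended there, such as APOL1 (at least 1.95-fold lower and limma adjusted p = 0.0436 between doses, 0.221 and 0.111 under those alternatives), PACSIN3 and PODXL. With the 24 h arrays normalized by themselves the fitted changes of these 3 genes stayed over 2-fold, on a side not detected, so only their calls were lost there.

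At 6 h, GSK-J4 at 2000 nM raised 59 genes and lowered 5 in JJN-3 and raised 30 and lowered 4 in RPMI. In JJN-3 the highest were MT1G (4.01, SE 0.304, limma adjusted p = 0.000774), INHBE (3.80), DDIT4, an inhibitor of mTORC1 (2.88, SE 0.155, limma adjusted p = 0.000365), and CHAC1, at least 5.52-fold higher. MT2A rose by 1.95 (SE 0.124, limma adjusted p = 0.000365). The lowered genes included HSPA1B (−0.94), TUBB4B (−0.92), the TNF receptor gene TNFRSF1B (−0.86), the hyaluronidase gene HYAL2 (−0.83) and RTKN (−0.85), the last of which did not pass with plain quantile normalization (0.116). In RPMI the highest were metallothioneins, with MT2A higher by 5.55 (SE 0.124, limma adjusted p = 2.11e-07), MT1G by 5.29, MT1F by 3.95, and MT1H at least 69.2-fold. The lowered genes included CSTF1 (−1.17), TNNI3K (−1.13) and the copper transporter gene SLC31A2 (−0.98). Integrated stress response genes rose at 9 of 14 in JJN-3 and 6 of 14 in RPMI (13, and 12 with 1 lower, adjusted over the list alone), amino acid supply genes at 11 and 5 of 19 (17 and 17 alone), and metal response genes at 7 of 9 in each (8 with 1 lower, and 7 with 1 lower). Of the calls 92.2% in JJN-3 and 88.2% in RPMI were upward, against 73.1% of 208 and 62.9% of 280 with the authors' processed values, and 75% of 104 in RPMI with plain quantile normalization. The JJN-3 count was 134 with plain quantile normalization and 42 without the 24 h DMSO array.

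The response to GSK-J4 was tested for a difference between lines and between times. Between lines at 6 h, MT2A rose less in JJN-3 than in RPMI (log2 difference −3.60, limma adjusted p = 0.00016), as did MT1E (−3.80). MT1H and GPR18, a G protein-coupled receptor gene, were the other 2 of 4 genes that passed, of 742 at an unadjusted p under 0.05. MT1H was detected in no control array of either line and GPR18 in no RPMI array compared, so the size of their differences is not known. Between 24 h and 6 h in JJN-3, 7 genes rose more at 24 h, all of them metallothioneins, including MT1G (4.86), MT2A (4.34, limma adjusted p = 2.6e-05), MT1E (4.07) and MT1X (2.17), and 2 were lower, PFKFB4 (limma adjusted p = 5.28e-05) and GPR18, of 830 at an unadjusted p under 0.05. MT1H, MT1F, MT1M, PFKFB4 and GPR18 were not detected on at least 1 side of these comparisons, so no size is given for them, and GPR18 did not pass with plain quantile normalization (limma adjusted p = 0.0793) nor MT1F with the authors' processed values (limma adjusted p = 0.175). MT1G and MT1E were detected on only 1 of 3 control arrays at 24 h, so their sizes between times are uncertain. DDIT3 passed neither test (0.16 between lines, 95% confidence interval −0.459 to 0.786). It was detected on no control array at 24 h, so no size is given for its difference between times. The upward share of 77.8% was 53.8% with plain quantile normalization, 33.3% of 21 with the authors' processed values and 66.7% with the times normalized separately, and the count between lines was 8 and 10 under the first and second of these. The 24 h and 6 h arrays form separate sets in the deposited tables, and whether they were run together is not given in the sources used here, so a difference between times may also hold one between sets.

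**Figure D2:**
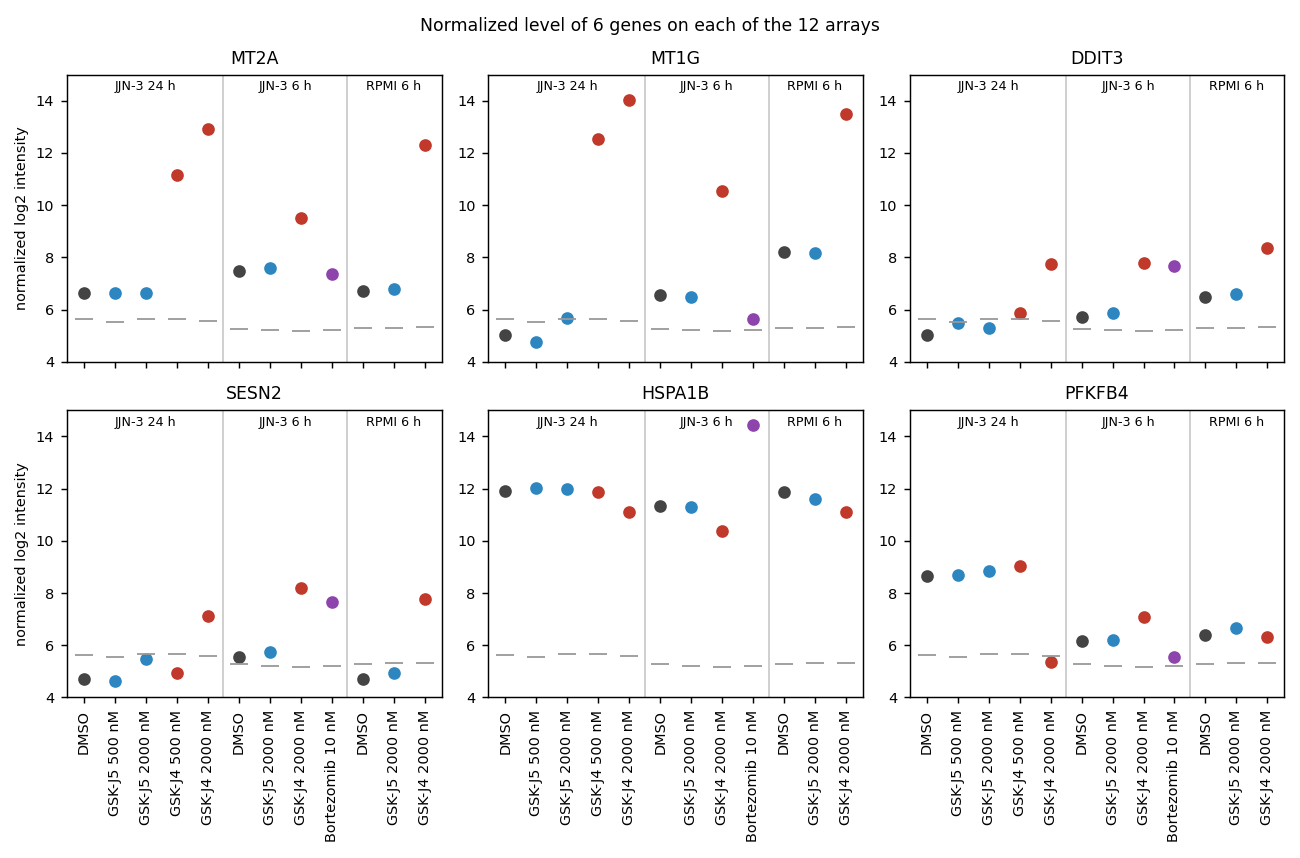
Normalized log2 intensity (vertical axis) of MT2A, MT1G, DDIT3, SESN2, HSPA1B and PFKFB4 on each of the 12 arrays, with grey dashes at the lowest detected level of each array. MT2A was higher by 6.30 with 2000 nM and 4.52 with 500 nM GSK-J4 at 24 h than on the DMSO array, while HSPA1B rose with bortezomib.

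Bortezomib at 10 nM for 6 h, a proteasome inhibitor in clinical use against myeloma, changed more genes than any other treatment tested here. HSPA6, a strictly stress-induced HSP70 gene, was at least 39.6-fold higher (limma adjusted p = 1.01e-05, other probe 3.41), its co-chaperone DNAJB1 12.9-fold (log2 change 3.69, SE 0.144, limma adjusted p = 1.01e-05), and HMOX1, heme oxygenase, 12.6-fold (3.65, SE 0.277, limma adjusted p = 0.000342). BAG3 (3.20), HSPA1B (3.14), the arsenite-inducible gene ZFAND2A (3.14), the autophagy gene GABARAPL1 (3.20), RBM11 (2.43), DDIT4 (2.33) and the antioxidant gene SRXN1 (2.31) followed. Heat shock genes rose at 11 of 16 measured (14 adjusted over the list alone) and proteasome subunits at 16 of 27 (17 alone), among them PSMD12 (2.46-fold), PSMC6 (1.08) and PSMD1 (1.06), with list medians of 1.05 and 0.53 against DMSO, above 100% of 10000 random lists of like expression. Endoplasmic reticulum chaperone and degradation genes rose at 6 of 19 (13 alone; HSPA5 1.27, HYOU1 0.96), antioxidant genes at 5 of 10 (6 alone; GCLM 1.61, TXNRD1 1.23), integrated stress response genes at 8 of 14 (10 alone), amino acid supply genes at 12 of 19 (14 alone; CTH 2.16), tRNA charging genes at 4 of 18 (5 alone) and autophagy genes at 5 of 16 (6 alone; MAP1LC3B 1.34, SQSTM1 1.32).

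The genes lowered by bortezomib included the receptor signaling antagonist SPRY1 (4.00-fold lower, limma adjusted p = 0.00027), the B-lineage transcription factor BCL11A (−1.96), the Notch target HEY1 (−1.72), KISS1R (−1.86), DLK2 (−1.78), ASTE1 (−1.66), PRAG1 (at least 3.08-fold lower), LRRC26, RPRML (at least 4.04-fold lower) and POU3F2 (at least 2.57-fold lower). Other detected probes gave −0.07 for HEY1, −0.09 for DLK2, −0.31 and −1.73 for BCL11A, and −0.09 and −1.58 for LRRC26, and of the 20 genes chosen by size 9 had another detected probe, 6 of which showed under 50% of the change. Of 18 measured plasma cell and myeloma genes 5 fell (5 adjusted over the list alone), with the syndecan SDC1 at −1.22 (limma adjusted p = 0.00153), the lenalidomide target IKZF1 at −1.03, the oncogene MAF at −0.98 and TENT5C at −0.97. Unlike with GSK-J4, no metallothionein rose, and MT1X (−1.16, limma adjusted p = 0.00497) and MT1F (−0.82) fell, 2 of 9 genes of the metal response list (3 alone), while MT2A was at −0.19 (limma adjusted p = 0.383). KDM6A was higher by 0.86 (SE 0.161, limma adjusted p = 0.0121). In all, 652 genes rose and 771 fell, 328 of them by more than 2-fold, and the count was 2599 with the authors' processed values.

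Bortezomib and GSK-J4 were set against each other in JJN-3 at 6 h, where 368 genes were higher and 473 lower with bortezomib. Heat shock genes were higher with bortezomib at 13 of 16 measured (15 adjusted over the list alone), proteasome subunits at 11 of 27 (20 alone), endoplasmic reticulum chaperone genes at 6 of 19 (13 alone) and antioxidant genes at 4 of 10 (6 alone), with HSPA6 at least 41.3-fold higher and HSPA1B (4.08), DNAJB1 (3.96), BAG3 (3.82) and HMOX1 (3.55) at the top. Metal response genes were lower at 7 of 9 (1 higher and 8 lower alone), among them MT1G (−4.92), MT1F (−3.45), MT1E (−2.40) and MT2A (−2.14), and GPR18 was at least 3.93-fold lower. DDIT3 was not separated (−0.08, 95% confidence interval −0.588 to 0.428). The integrated stress response list had 1 gene higher and 3 lower of 14 (1 and 7 alone), and amino acid supply 3 lower of 19 (5 alone). The count was 1409 with plain quantile normalization and 1970 with the authors' processed values.

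Genes over 2-fold from DMSO were shared beyond independence, with 23 raised by both compounds among 206 and 57 (1.11 expected) and 2 lowered by both among 163 and 10 (0.155 expected), where the shared DMSO array adds to the overlap. When GSK-J5 replaced DMSO as the control of GSK-J4, 18 were raised by both among 206 and 52 (1.02 expected) and 0 lowered by both among 163 and 1 (0.0155 expected). Across 10546 genes, which are not independent replicates, the changes had r = 0.367 and rho = 0.373 with the DMSO array shared (covariance 0.0503, against 0.0228 and r = 0.5 in simulated unchanged groups that share a control). With GSK-J5 as the control of GSK-J4, so that no array was shared, r was 0.124 and rho 0.073 (covariance 0.0153, simulated r −0.001).

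**Figure D3:**
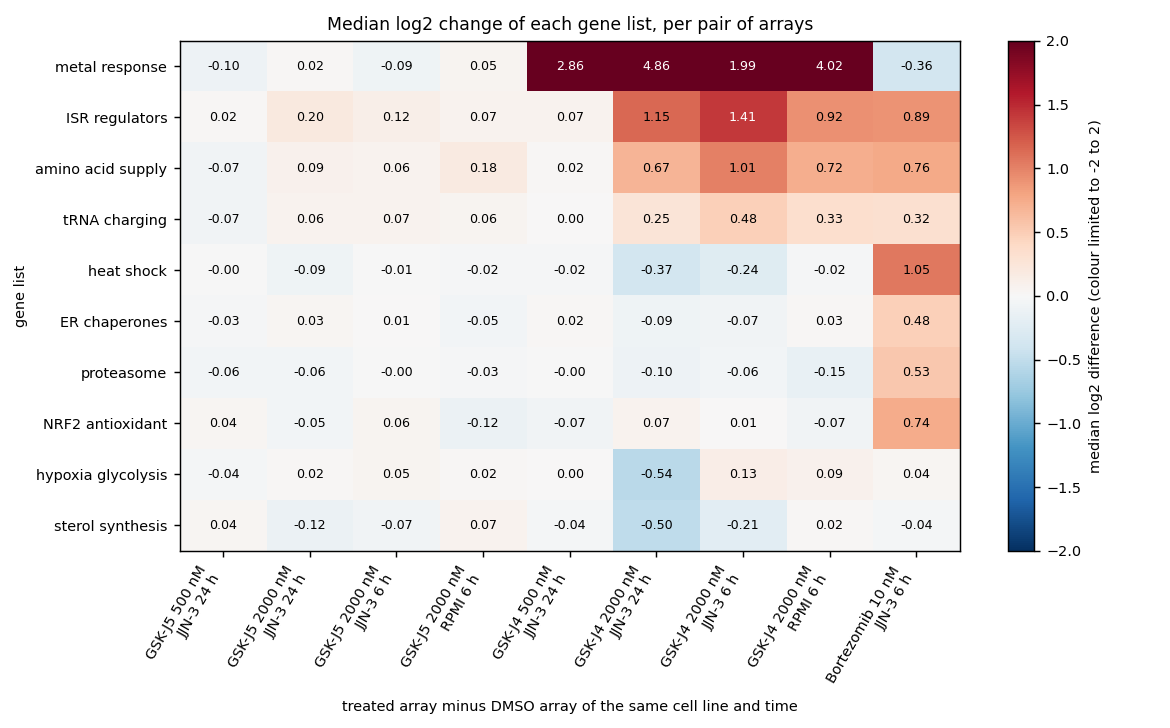
Colours give the median log2 change (treated array minus the DMSO array of the same line and time, limited to −2 to 2) of 10 gene lists in 9 pairs of arrays. The metal response list is high in all 4 GSK-J4 pairs, and the heat shock (1.05) and proteasome (0.53) lists are highest with bortezomib.

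Counts of genes over 2-fold between a single treated array and its DMSO array had no test, and the GSK-J5 arrays gave their background. GSK-J4 at 2000 nM had 86 genes higher and 55 lower in JJN-3 at 24 h, 57 and 10 in JJN-3 at 6 h, and 50 and 20 in RPMI, and at 500 nM 26 and 32 (6 and 0 with the authors' processed values). Bortezomib had 206 and 163. GSK-J5 at 2000 nM had 20 and 30, 1 and 6, and 3 and 10 in the same contexts, and at 500 nM 23 and 20. All of these counts shrank with the authors' processed values, to 25 for GSK-J4 and 0 for GSK-J5 at 2000 nM in JJN-3 at 24 h.

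JJN-3 and RPMI differed widely at 6 h, with 3954 genes higher and 3175 lower in JJN-3, 2452 of them by more than 2-fold. HLA-DRB1, which encodes an antigen-presenting protein, was at least 290-fold higher in JJN-3 (n = 3 arrays per line, limma adjusted p = 1.64e-11) and HLA-DRB5 at least 205-fold. HLA-DRB4 was higher by 7.28 on its main probe and at −0.16 on its other probe. FAF1, a ubiquitin-binding apoptosis gene, was at least 54.2-fold higher, and by 4.82 on its other probe. The cancer-testis antigens GAGE12J (at least 493-fold lower in JJN-3), GAGE12F (at least 396-fold lower) and GAGE12G were high in RPMI, where near-identical copies make the single member uncertain. Of 18 plasma cell and myeloma genes 6 were higher and 4 lower in JJN-3 (6 and 4 adjusted over the list alone), with the BCMA gene TNFRSF17 (2.07) and POU2AF1 (1.82) higher and MAF (−2.50), CD38 (−2.46) and MZB1 (−1.85) lower. The lists were not tested as groups here, and 7129 of all 11459 genes passed. HOX genes were higher at 6 of 9 and lower at 1 (6 and 1 alone). The metal response list had 0 higher and 4 of 9 lower (4 alone), including SLC30A1 (−2.41). This comparison averages the DMSO, GSK-J5 and GSK-J4 arrays of each line. Over 6 metallothioneins the median RPMI minus JJN-3 difference was 0.00345 on the DMSO arrays and 2.86 on the GSK-J4 arrays. For genes that respond to GSK-J4, these values can therefore hold a difference in response as well as one between lines. KDM6A was at least 2.41-fold higher in JJN-3, MYC was at −0.17, IRF4 was higher by 0.68 and DDIT3 lower (−0.70).

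Between 24 h and 6 h in JJN-3, 1949 genes were higher and 3125 lower at 24 h, 805 of them by more than 2-fold. A difference between the 2 sets of arrays cannot be told from time here. The DMSO, GSK-J5 and GSK-J4 arrays of each time were averaged, as in the comparison of lines. The fetal globin genes HBG1 (3.68, SE 0.151) and HBG2 (3.43) were highest, and of 6 erythroid marker genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone). The T cell surface gene CD6 (2.16), TINAG (2.28) and the cancer-testis gene SPANXA1 (at least 3.69-fold higher) followed. Structural RNAs were lowest at 24 h, with RNA18SN5 at −4.61 (SE 0.236) and RNA28SN5 at −3.59, both ribosomal RNAs, whose signal depends on RNA preparation and labelling, and RNY4 at least 9.08-fold lower, beside S100A4 at least 9.00-fold lower and JAM2 (−3.39). The mean of RNA28SN5 over the contexts was also higher with GSK-J4 than with DMSO, by 1.12, and by 0.69 on its other probe. Those 2 values are differences of means given without a test, so whether this ribosomal signal depends on treatment is not settled. MYC was higher at 24 h by 0.52 (limma adjusted p = 0.00314). Sterol synthesis genes were higher at 6 of 11 and lower at 2, antioxidant genes higher at 6 of 10, and HOX genes lower at 6 of 9, with the same counts adjusted over each list alone. The median of all genes shifted by −0.30 with the authors' processed values and by −0.62 with the sets normalized separately, so these are differences relative to the other genes. The count was 3358 without the GSK-J5 arrays.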

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

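The response to GSK-J4 was compared between lines and times by planned tests, while the tests of explanations in the next 3 paragraphs were chosen only after the results were seen.

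The metallothionein rise with 2000 nM GSK-J4 at 6 h was smaller in JJN-3 than in RPMI, by −3.599 for MT2A and −3.801 for MT1E on the log2 scale, and MT1H passed too (limma adjusted p = 0.00114), with no size because it was detected in no control array of either line. A higher starting level in JJN-3 would leave the treated levels alike. Over the 6 metallothioneins raised across contexts the treated levels were instead higher in RPMI by a median of 2.865 (quartiles 2.18 to 3.57, all 6 genes). On the DMSO arrays the median was 0.00345 (quartiles −0.542 to 0.279, 3 of 6 genes higher in RPMI). There MT2A (−0.768) and MT1F (−0.663) were higher in JJN-3 and MT1G (1.63) in RPMI, and MT1H counts in that median though not detected. With GSK-J4, MT2A was higher in RPMI by 2.80. A weaker response of that whole JJN-3 culture would lower the stress genes too, but 23 integrated stress response and amino acid genes rose more in JJN-3 by a median of 0.211 (quartiles 0.137 to 0.483). Those genes had passed across contexts, a choice that favours genes with like changes in both lines. Over all measured genes, passed or not, the median differences were 0.266 for integrated stress response (14 genes) and 0.202 for amino acid supply (19 genes). What stays open is a difference between the lines in metallothionein induction, which may be biological, and any difference of the single cultures that acts on metallothioneins alone.

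At 500 nM in JJN-3 the metallothioneins rose and no integrated stress response or amino acid gene passed, and the median ratio of 500 nM to 2000 nM changes was higher for the metallothioneins by 0.678 (0.682 against 0.0034), where a single smaller effect on all genes would keep the ratios alike. Of the 7 metallothioneins in that ratio, MT1H, MT1F and MT1M were detected on no control array at 24 h, so their ratios are uncertain. Both sets of genes were chosen as passing at 2000 nM. Over all measured genes the median change at 500 nM was 0.031 for integrated stress response and −0.014 for amino acid supply. Something shared by the 500 nM cultures would also act with GSK-J5, but there the median of 7 metallothioneins was −0.103 (quartiles −0.179 to −0.049). RNA from the 2000 nM culture mixed into the 500 nM sample, at the share of 24.1% that the metallothioneins would need, predicts a median change of 0.478 for 13 stress and amino acid genes. The observed median was 0.0045 (quartiles −0.0316 to 0.0288), below the prediction by −0.483 (13 of 13 genes) and below the lower quartile of 0.304 predicted at a share of 18.9%, which speaks against mixing. A first bound of 0.5 exceeded the predicted change and could not be met, so it was replaced after the values were seen, and what stays open is a lower dose threshold of the metallothioneins, which these single cultures may reflect.

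Hypoxia and glycolysis genes were lower in the JJN-3 array with 2000 nM GSK-J4 at 24 h. Quantile normalization gave all arrays the same distribution, so a lower signal of that array as a whole was removed beforehand and could not be tested. The list's median lay at percentile 0 of 10000 matched random lists (17 genes, random medians −0.147 to 0.105). This shows only that the list was lower than genes of like level. The change at 24 h differed from that at 6 h by a median of −0.614 (quartiles −0.832 to −0.355). With 1 culture at that dose and time, a difference in oxygen or cell density of that culture cannot be told apart from an effect of GSK-J4, which could also depend on time, and each time is a separate set of arrays.

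Other genes differed in their response to GSK-J4 between groups by the tests of the difference. Metallothioneins rose more at 24 h than at 6 h in JJN-3, with log2 differences of 4.862 for MT1G, 4.337 for MT2A, 4.068 for MT1E and 2.175 for MT1X. The sizes for MT1G and MT1E are uncertain, because each was detected on only 1 of 3 control arrays at 24 h. Genes not detected on at least 1 side passed the tests without a size. They were GPR18 between lines (limma adjusted p = 0.0399), and between times MT1H (limma adjusted p = 4.41e-05), PFKFB4 (5.28e-05), MT1F (0.00761, and 0.175 with the authors' processed values), MT1M (0.0137) and GPR18 (0.0251, and 0.0793 with plain quantile normalization). Among 5033 detected probes without a gene name, which the comparisons leave out, 5 rose with GSK-J4 across contexts and 0 with GSK-J5, the largest by 1.84.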

How the results depend on the processing

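The 24 h and 6 h arrays normalized separately, and the rows before the first break alone, were alternatives chosen after seeing the data. Single named genes were followed only under the other normalizations, where none that had passed changed sign. Lists were also followed with an estimated correlation and with a context left out, and none that passed both times changed direction. Sign changes of genes that had not passed were not counted, and other probes of a gene were not part of this check. The majority direction turned in some counts. The cause of the changes in counts was not tested except where fewer arrays or more genes were tested by construction. Detection in at least 3 arrays, all named probes tested, and all 12 arrays in the fit (identical by construction for the contrasts it shares) kept every count within 1.5 times. Of the 90 genes called for GSK-J4 against DMSO, quantile normalization kept 89, the authors' values 81, the trend 89 and no filter 51. Signal over background limits the dim genes, most of all on the 24 h arrays, which detected 13837 to 14378 probes against 15601 to 16581 at 6 h. The slide block was not run because no slide is given, and the authors' values and separate normalization were not used to count genes for 24 h against 6 h, because the 2 sets were normalized apart, and gave only the shift of the median gene. With only the rows before the first break, 13 of 14 counts stayed within 1.5 times of their share, and GSK-J4 in RPMI moved to 5.

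With quantile normalization the counts became 315 for GSK-J4 against DMSO, 156 for GSK-J4 against GSK-J5, 267 for GSK-J4 2000 nM in JJN-3 at 24 h, 134 in JJN-3 at 6 h, 104 in RPMI, 125 between doses, 8 for the line difference and 1409 for bortezomib against GSK-J4. With the authors' processed values they became 251, 142, 208 in JJN-3 at 6 h, 280 in RPMI, 2599 for bortezomib, 10 for the line difference, 21 for the time difference and 1970 for bortezomib against GSK-J4. With separate normalization RPMI gave 55 and the doses 46. With no filter on dim probes GSK-J4 gave 51 against DMSO, 21 against GSK-J5 and 24 between doses. With an intensity trend the counts were 259, 124, 242 in JJN-3 at 24 h, 102 at 6 h and 70 in RPMI. With no context block both GSK-J4 against DMSO and against GSK-J5 gave 0. Leaving out 1 context gave 12 to 40 for GSK-J4 against DMSO and 5 to 30 against GSK-J5. Leaving out 1 treatment gave 3358 to 3962 for 24 h against 6 h, and leaving out 1 control array of 24 h gave 42 to 56 for GSK-J4 in JJN-3 at 6 h.

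Genes over 2-fold with quantile normalization, the authors' values and separate normalization were 37 (34 higher), 25 (24 higher) and 69 (54 higher) for GSK-J4 2000 nM in JJN-3 at 24 h, 8 (6 higher), 6 (6 higher) and 21 at 500 nM, 2 (0 higher), 0 and 8 for GSK-J5 2000 nM, and 1 (0 higher), 0 and 7 at 500 nM. At 6 h in JJN-3, bortezomib gave 158 and 164 (109 higher) under the first and second, GSK-J4 35 (all higher) and 36 (all higher), and GSK-J5 2 and 2 (0 higher), and 13 (5 higher) with separate normalization. In RPMI, GSK-J4 gave 32 (28 higher) and 33 (28 higher), 43 with the GSK-J5 array as control, and GSK-J5 gave 3 and 3 (2 higher), and 24 with separate normalization. Limits of 1.5-fold and 3-fold gave 760 and 22, 387 and 7, 385 and 1, and 388 and 0 for the 24 h arrays in that order, 1761 and 52 for bortezomib, 460 and 21 for GSK-J4 and 194 and 0 for GSK-J5 in JJN-3 at 6 h, and 621 and 21 and 205 and 2 in RPMI. The majority turned for the time difference (7 higher and 2 lower, and 7 and 14 with the authors' values) and for GSK-J4 at 500 nM (26 and 32, and 6 and 2, 6 and 0, and 11 and 10 under the 3 normalizations, 227 and 160 at 1.5-fold, 6 and 1 at 3-fold, 33 and 26 with the GSK-J5 array as control). It also turned for GSK-J5 at 500 nM (23 and 20, and 0 and 1 with quantile normalization, 16 and 17 with detection in 3 arrays) and in RPMI (3 and 10, and 2 and 1 with quantile normalization and with the authors' values). At 1.5-fold it turned for GSK-J5 at 2000 nM in JJN-3 (194 and 191 at 24 h, 98 and 96 at 6 h) and for bortezomib (875 and 886). The correlation of bortezomib with GSK-J4 was 0.349, 0.347 and 0.373 with the DMSO array shared and 0.131, 0.136 and 0.12 with GSK-J5 as control. With an estimated correlation 0 of the 10 lists for GSK-J4 against DMSO and 0 of the 9 against GSK-J5 passed, and for GSK-J5 1 list passed with quantile normalization and 1 with the authors' values.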

Other observations

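Bortezomib also changed genes outside the stress lists in JJN-3 at 6 h. It changed many of all genes, and these lists were not tested as groups by camera. A few members passing in a list may therefore be no more than the share over all genes. Low percentiles among random lists also occurred with GSK-J5 at 500 nM, where the respiratory chain list lay at 0.2. HOX genes, developmental transcription factors, fell at 2 of 9 measured (4 adjusted over the list alone), with HOXB2 at −1.33 (limma adjusted p = 0.0016) and HOXB4 at least 1.43-fold lower, and their median of −0.62 against DMSO lay at percentile 0.03 of 10000 random lists of like expression. NF-kB targets fell at 3 of 10 (3 alone), with NFKBIA, the inhibitor of NF-kB, at −0.70 and CD83 at −0.63 beside NFKBIE. Among p53 targets the cell cycle inhibitor CDKN1A (limma adjusted p = 0.000574) and GADD45A (1.66) rose and XPC, a DNA repair gene, fell (−0.65), 2 and 1 of 10. Immediate early genes split, with 2 of 12 rising, among them MAFF (1.25), and 2 falling, among them KLF2 (−1.35). Of 15 demethylase and polycomb genes KDM2A (0.90) and KDM6A (0.86) rose and KDM2B fell (−0.84). PMAIP1, which promotes apoptosis, rose by 1.05, and the sterol synthesis genes MVD (0.86) and HMGCS1 (0.77) rose, 2 of 11. IFI44 was at least 2.22-fold higher and IFITM1 lower (−0.78), 1 and 1 of 12 interferon response genes. No gene of the respiratory chain (19) or ribosomal protein (22) lists passed, and the reference gene TBP rose by 0.78.

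Between the lines at 6 h, further genes differed. The lymphotoxin gene LTB was at least 19.2-fold and the antiviral gene MX1 at least 14-fold lower in JJN-3, the small heat shock gene HSPB1 was at −3.86, the glucose transporter gene SLC2A3 at least 7.50-fold lower and the mitophagy gene BNIP3 at least 10.9-fold lower. TNFAIP3, a brake on NF-kB, was higher by 3.50, and HOXB2 at least 6.69-fold.

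The splits of arrays were planned. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The splits ignored the pairing of arrays by context or treatment, and every other split leaves any real difference in the residual. A count of 0 in them is therefore no measure of chance. The real split gave 90 genes for GSK-J4 against DMSO, 46 for GSK-J4 against GSK-J5, 7129 for JJN-3 against RPMI and 5074 for 24 h against 6 h, where the highest other split gave 0, so 1 of 10 splits was as large. For GSK-J5 against DMSO the real split gave 0 and so did the highest other, so 10 of 10 were as large.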
